A study of Mus musculus with 16 samples.

How the data were processed

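Kidneys of 7 wild-type and 9 Aqp11 knockout pups aged 7 days were each hybridised to an Affymetrix mouse whole-genome array of 45101 probe sets, 64 of them controls. Genotype, sex and sample number were taken from the labels, and each array holds the RNA of a separate animal per the labels' protocols. The deposited values are signal intensity on a linear scale, from 0.0256 to 14264, which the authors obtained with GCOS 1.3 per the submitters' processing notes. Whether they were scaled between arrays is not given in the sources used here. The 2% trimmed means differed 2.12-fold between arrays, beyond the 5% set as the limit for values already scaled, so the intensities were quantile normalized. Values under the 20th percentile of all values (a signal of 6.89, or 2.78 in log2) were then set to it, and log2 was taken. A floor understates the change of dim genes. Quantile normalization assumes that arrays share a distribution, and would hide a change in total mRNA.

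Probe sets were named from the platform annotation given with the data, which lists 35890 of them. Of these, 34958 name 1 gene and 932 several. The 9211 probe sets that the annotation does not list are unnamed here. The names cover 18194 genes. Gene identifiers of 34754 probe sets matched the RefSeq table of assembly GRCm38.p6 and 204 did not. That table served for current symbols and the order of genes along a chromosome. The build behind the array design is not given in the sources used here, so no coordinates are printed. Each gene was represented by its brightest probe set over all 16 arrays, among probe sets naming 1 gene. It was tested if above its array's 40th percentile on at least 7 of the 16 arrays, which left 12500 genes.

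Knockout was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, genotype as the only term) and Benjamini-Hochberg adjustment over all genes tested at 0.05. Single measures used exact permutation of the genotype labels. Of 29 gene lists fixed before the data were examined, the 26 with at least 5 tested genes, apart from the sex-linked genes, were tested with camera at a preset correlation of 0.01. An estimated correlation and fry served as alternatives. Fry tests whether a list moves on balance, without setting it against other genes. Sex entered as a second term for the sex effect and as an interaction. Changed genes among the 50 tested genes on each side of Aqp11 were set against all others with Fisher's exact test.

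Named genes follow a rule fixed before the data were examined. It takes Aqp11, the 12 largest rises and the 12 largest falls among changed genes with every knockout array on the same side of the wild-type mean, Pkd1, Pkd2 and Pkhd1, up to 4 members with the smallest p from each list described, up to 8 changed neighbours of Aqp11, and the sex-linked genes. Trim34a and Trim12a are named under the rule for falls. Fga and Fgb are named outside the rule, to set beside Fgg. Genes named only in the closing section for lists written later were chosen after their values were seen.

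The fit was tested on values simulated from each gene's mean and residual SD, with 200 genes changed. For knockout against wild type over 12500 genes it recovered 62.7% of log2 changes of 0.5, 86.6% of changes of 1 and 100% of changes of 2, with 10 false among 176 calls. The interaction test recovered 94.5% of log2 changes of 2. Genes were simulated independently, without the structure that genes share across the real arrays, so these rates need not hold for the real fits. The alternatives were other normalizations, floors and filters, other ways to combine probe sets, sex and the first sample number as terms, other variance models, each array left out and each sex alone. Alternatives on array brightness and RNA quality were added after seeing the data. The brighter and dimmer arrays were parted at the widest gap in log2 trimmed mean signal. Figures were drawn with matplotlib.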

Results

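Kidney RNA was measured in 16 mouse pups aged 7 days, 7 wild type and 9 lacking Aqp11, with 1 array per animal. The wild-type pups were 3 males and 4 females and the knockout pups 5 males and 4 females. Aqp11 encodes an aquaporin of the endoplasmic reticulum, and the comparison asks how its loss changes gene expression in the kidney. The trimmed mean signal of an array varied 2.12-fold, with 165 ± 33.4 (SD, n = 7) in wild type and 169 ± 44.9 (SD, n = 9) in knockout, a difference smaller than the spread between animals (exact permutation p = 0.85, two-sided). After normalization, the first principal component held 29.9% of the variance between arrays and separated the genotypes, from -27.5 to -13.8 in wild type and from 10.4 to 25.2 in knockout. The second held 17.6% and did not differ between genotypes (exact permutation p = 0.84, two-sided). For arrays, the number of animals limits the precision.

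Aqp11 itself was nearly lost in the knockout. Its brightest probe set had a log2 signal of 7.87 ± 0.16 (SD, n = 7) in wild type and 2.95 ± 0.33 (SD, n = 9) in knockout, where 7 of the 9 arrays lay at the floor set on low signals. The change was therefore at least 30.3-fold (limma adjusted p = 3.89e-14; exact permutation p = 8.74e-05, two-sided, the smallest these groups can give). The other probe sets of Aqp11 were also lower, by 1.75 on the log2 scale (-1.75, exact permutation p = 0.0021) and by 1.28 (-1.28, exact permutation p = 8.74e-05), so each array carried the genotype its label gives.

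**Figure D1:**
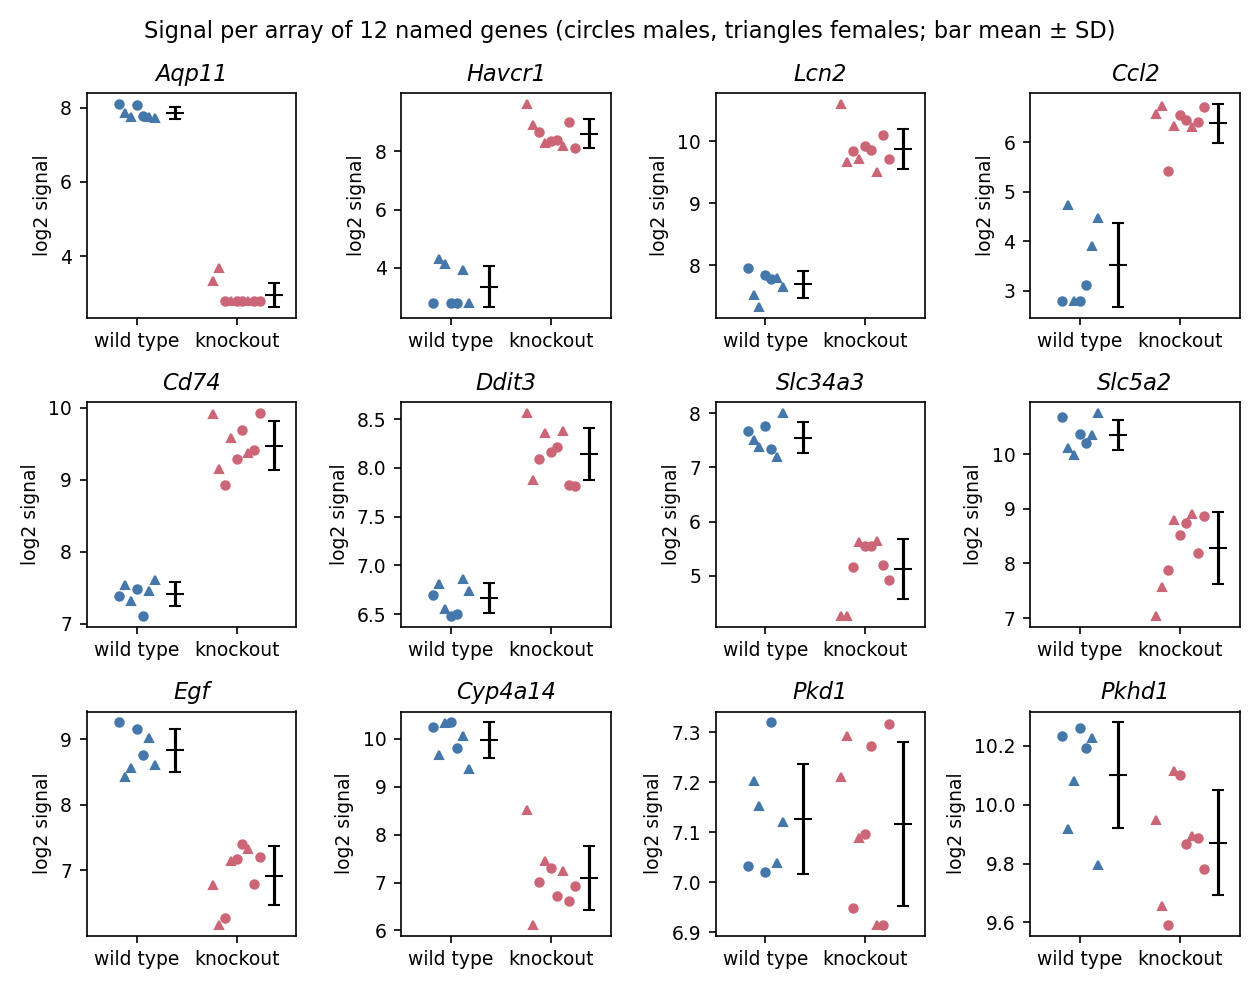
Log2 signal of 12 named genes on each array, for wild type (blue, n = 7) and knockout (red, n = 9). Circles are males, triangles females, and the black bar is the mean ± SD. Aqp11 lies between 7.72 and 8.11 in wild type and between 2.78 and 3.69 in knockout, while the groups overlap for Pkd1 and Pkhd1.

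Genes of tubule injury, inflammation and endoplasmic reticulum stress were among the 12 largest rises of named genes in the knockout kidney, and the proximal tubule transporter genes Slc34a3 and Slc5a2 were among the 12 largest falls. Havcr1, a marker of injured proximal tubule, went from 3.35 ± 0.72 (SD, n = 7) to 8.61 ± 0.50 (SD, n = 9), at least 38.4-fold, since 4 wild-type arrays lay at the floor. Among probe sets that name 1 gene, the next largest rises were those of Serpinb9b (13.4-fold), Mmp12 (12.7-fold), Egr2 (10.3-fold), Fgg (9.72-fold), Krt20 (9.69-fold), Sprr2f (9.09-fold) and Ankrd1 (8.7-fold). Mmp12 encodes a macrophage elastase, Egr2 an inducible transcription factor, Fgg the gamma chain of fibrinogen and Krt20 an epithelial keratin. Pmaip1, which encodes a protein that promotes apoptosis, rose 7.54-fold, and the chemokine gene Ccl2 rose 7.35-fold. Derl3 (6.7-fold) and Trib3 (6.64-fold), both induced by endoplasmic reticulum stress, completed the 12 largest rises. For each of these 12 genes, all 9 knockout arrays lay above the wild-type mean. Wild-type arrays lay at the floor for Serpinb9b and Mmp12 (4 each), Ccl2 (3) and Egr2, Krt20, Ankrd1, Derl3 and Trib3 (1 each), so their folds are lower bounds too, and the order of the rises holds only for this floor.

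Besides Aqp11, the largest falls among probe sets that name 1 gene were those of Trim34a (7.74-fold), Cyp4a14 (7.34-fold), Trim12a (6.72-fold), the phosphate transporter gene Slc34a3 (5.36-fold) and the bile acid transporter gene Slc10a1 (5.35-fold). Cyp4a14 encodes a fatty acid hydroxylase. Prss35 fell 4.36-fold, the glucose transporter gene Slc5a2 4.21-fold, F13b 4.1-fold and Egf 3.77-fold. Crabp1 (3.58-fold) and Ugt3a2 (3.22-fold) were the last of the 12. The folds of Trim12a, Crabp1 and Trim34a are lower bounds, with 5, 2 and 1 knockout arrays at the floor. Knockout array 4-3 was the highest knockout for both Trim genes. Its Trim34a signal of 6.71 lay inside the wild-type range (6.63 to 7.50), while the other knockout arrays lay at 2.78 to 4.94. Its Trim12a signal was 4.91, against 2.78 to 3.77 on the others. Trim34a and Trim12a lie close to Aqp11 in the gene order of its chromosome and belong to a family of related genes, so probe sets may not separate family members. Of the genes named by rank, by name or as members of a list, 50 had another tested probe set, and none of these passed the threshold in the opposite direction. Not all of them passed in the same direction either. For Ddit3, Kl, Jag1, Wnt4 and Glis2, among the changed genes named below, no other tested probe set passed.

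Of the 12500 genes tested, 2215 (17.7%) differed between genotypes, 1171 higher and 1044 lower in knockout. The change was at least 2-fold for 280 genes, 206 of them higher and 74 lower. For 668 of the changed genes no knockout array overlapped a wild-type array. Chance gives 0.0175% of genes, or 2.19 genes, without overlap. The arrays fell into 8 brighter and 8 dimmer ones, both with each genotype, and the counts were 1333 changed genes among the brighter arrays alone and 1183 among the dimmer. With the deposited scaling left as it was, 438 genes passed, 284 higher and 154 lower.

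Macrophage genes rose almost as a whole. Of 29 tested members, 28 rose and none fell, with a median log2 change of 1.37 (camera adjusted p = 1.48e-35, and adjusted p = 0.00888 with an estimated correlation). Adjusted over the list alone, 29 rose. The list's mean log2 signal was 6.42 to 6.54 on 5 wild-type arrays, 7.25 and 7.22 on wild-type arrays 2-1 and 2-2, which stood apart from these, and 7.86 to 8.52 on the knockout arrays. Cd74, the invariant chain of MHC class II, rose from 7.41 ± 0.17 (SD, n = 7) to 9.47 ± 0.34 (SD, n = 9), or 4.17-fold. The complement gene C1qa rose 3.31-fold, the Fc receptor gene Fcgr3 3.17-fold and the MHC class II gene H2-Aa 2.82-fold. Lymphocyte genes were mostly too dim to test. None of 4 tested members passed, neither over all genes nor adjusted over the list alone, and the smallest p among them belonged to Ighm (log2 change 0.38, adjusted p = 0.103), before Zap70 (0.42), Cd79b (-0.13) and Cd8a (-0.15).

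Genes of the tubular injury response rose in parallel. Of 32 tested members 25 rose and none fell, with a median log2 change of 1.04 (camera adjusted p = 3.93e-33, and adjusted p = 0.000853 with an estimated correlation), and 30 rose and 1 fell adjusted over the list alone. Besides Havcr1 and Fgg, Timp1, an inhibitor of metalloproteinases, rose 5.08-fold and Lcn2, the gene of a secreted injury marker, rose 4.53-fold. The other fibrinogen genes of the list, Fga (log2 change 0.36, limma adjusted p = 0.369) and Fgb (-0.58, limma adjusted p = 0.123), did not pass. Extracellular matrix and fibrosis genes rose for 27 of 38 members and fell for 1, with a median of 0.34 (camera adjusted p = 6.83e-17, and adjusted p = 0.00888 with an estimated correlation). Adjusted over the list alone, 29 of them rose and 2 fell. Among them were Tgfbi (1.78-fold), the collagen cross-linking enzyme gene Loxl1 (1.64-fold) and the matrix gene Fbln1 (2.04-fold). The macrophage list rose in the same kidneys.

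Endoplasmic reticulum stress genes rose for 24 of 37 members and fell for none, with a median log2 change of 0.36 (camera adjusted p = 9.47e-19, and adjusted p = 0.000853 with an estimated correlation). Adjusted over the list alone, 26 rose and 1 fell. Sdf2l1 of the lumenal folding machinery rose 3.28-fold, the asparagine synthetase gene Asns 3.21-fold and Ddit3, the gene of the stress factor CHOP, 2.79-fold, beside Trib3 and Derl3. Interferon response genes rose for 13 of 26 members and fell for none, with a median of 0.44 (camera adjusted p = 8.2e-09, and adjusted p = 0.0475 with an estimated correlation), and 19 rose and 1 fell adjusted over the list alone. These included H2-K1 (1.57-fold), Cxcl10 (2.63-fold), Oas1a (1.65-fold) and Oasl2 (1.92-fold). Among p53 targets 5 of 22 rose and none fell, with a median of 0.14 (camera adjusted p = 0.0025, and adjusted p = 0.0215 with an estimated correlation), and 6 rose adjusted over the list alone. Pmaip1 was the largest of these, while Btg2 (1.39-fold), Phlda3 (1.25-fold) and Gadd45a (1.34-fold) moved less. The p53 list missed the threshold in males alone (adjusted p = 0.089) and on the dimmer arrays alone (adjusted p = 0.0676), with a range from 5.02e-06 to 0.089 over its alternatives.

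Proximal tubule genes fell together. Of 40 tested members 35 fell and none rose, with a median log2 change of -0.67 (camera adjusted p = 1.87e-33, and adjusted p = 0.0215 with an estimated correlation), and 36 fell adjusted over the list alone. Beside Slc34a3 and Slc5a2, the organic anion transporter gene Slc22a8 fell 1.9-fold and Spp2 fell 1.88-fold. Genes of the thick ascending limb and distal tubule fell for 7 of 19 members and rose for none, with a median of -0.19 (camera adjusted p = 0.000201, and adjusted p = 0.0449 with an estimated correlation). Adjusted over the list alone, 7 fell and 1 rose. Egf led these falls, followed by Kl (1.74-fold), the coreceptor of a phosphate hormone, the claudin gene Cldn10 (1.38-fold) and the chloride channel subunit gene Bsnd (1.55-fold). Renin-angiotensin genes fell for 4 of 10 members, with the same 4 by adjustment over the list alone, a median of -0.20 and an adjusted p of 0.00327 (adjusted p = 0.035 with an estimated correlation). They were Anpep (1.31-fold), Ace (1.35-fold), Agtr1a (1.24-fold) and Ctsa (1.21-fold).

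**Figure D2:**
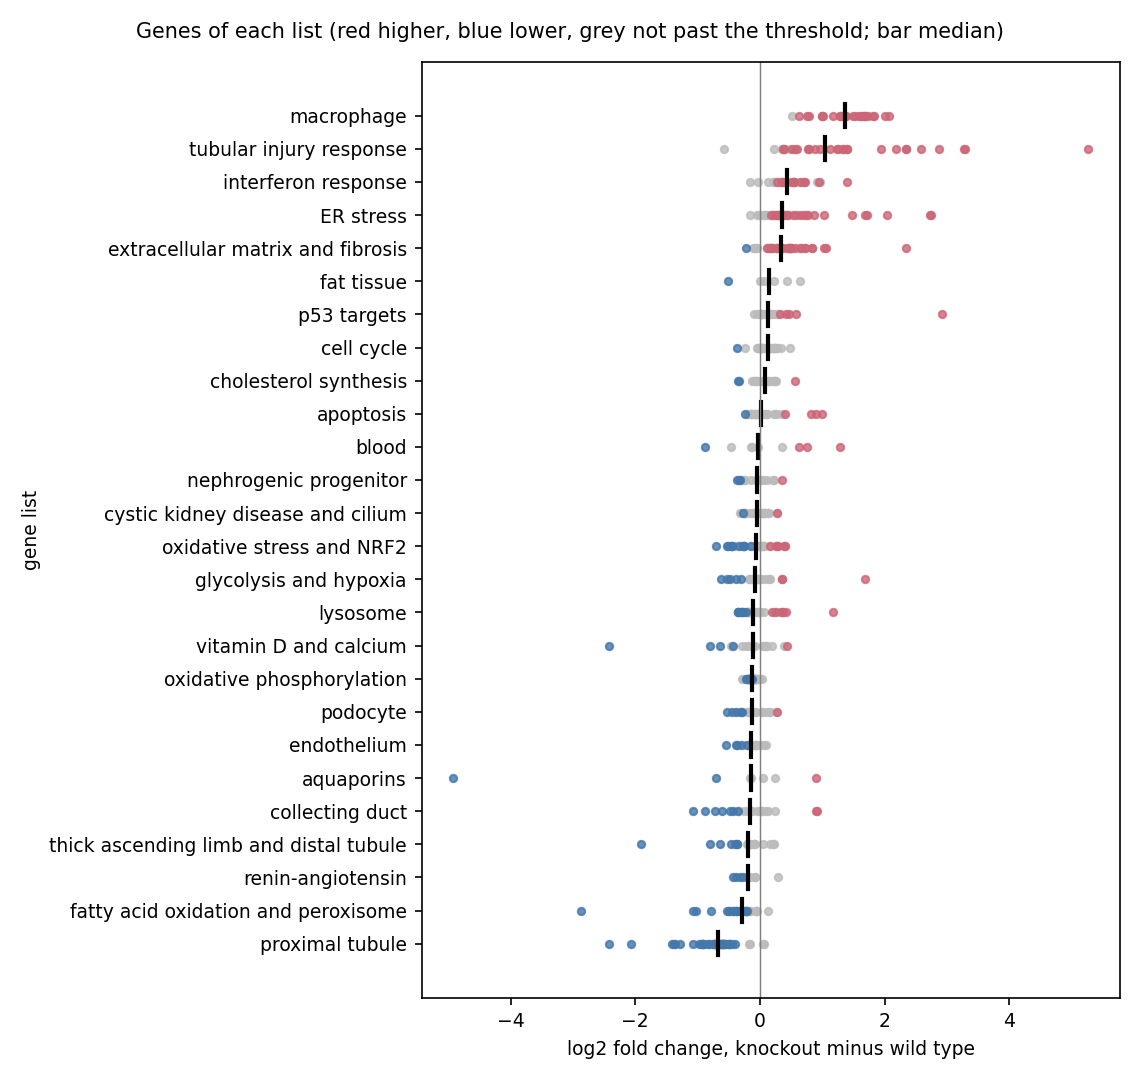
Log2 fold change, knockout minus wild type, of each tested gene (points) in the 26 tested gene lists, with the list median as a black bar. Red points rose, blue points fell and grey points did not pass the threshold. The macrophage list has the highest median (1.37) and the proximal tubule list the lowest (-0.67).

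Fatty acid oxidation and peroxisome genes fell for 18 of 29 members and rose for none, with a median of -0.29. Their camera adjusted p was 6.18e-13, but the adjusted p was 0.0592 with an estimated correlation, and 21 fell adjusted over the list alone. Cyp4a14, Ehhadh (2.1-fold), Acaa1b (1.72-fold) and Decr1 (1.41-fold) fell most clearly. Oxidative phosphorylation genes fell for 9 of 40 members by small amounts, with a median of -0.12 (camera adjusted p = 4.01e-08, but adjusted p = 0.235 with an estimated correlation). Adjusted over the list alone, 17 fell, led by Cox6c (1.15-fold), Cox4i1 (1.12-fold), Atp5o (1.15-fold) and Atp5c1 (1.11-fold). Endothelial genes fell for 5 of 21 members, also 5 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.000725, but adjusted p = 0.208 with an estimated correlation). They included Emcn (1.29-fold), Ehd3 (1.3-fold), Sox17 (1.46-fold) and Pecam1 (1.16-fold). In all, 13 of 26 lists passed with camera's preset correlation and 9 with an estimated one, and other splits of the arrays often gave as many with the preset correlation.

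Collecting duct genes went both ways. Of 22 members 2 rose and 7 fell, with a median of -0.17 (camera adjusted p = 0.0165, but adjusted p = 0.331 with an estimated correlation), and 2 rose and 9 fell adjusted over the list alone. The water channel gene of principal cells, Aqp2, rose 1.87-fold, from 10.15 ± 0.39 (SD, n = 7) to 11.05 ± 0.24 (SD, n = 9), and the potassium channel subunit gene Kcne1 rose 1.88-fold. Slc4a1, the anion exchanger of intercalated cells, fell 1.83-fold and the ammonium transporter gene Rhbg fell 1.65-fold. The list's call was lost in males alone (adjusted p = 0.477) and on the dimmer arrays alone (adjusted p = 0.0524), and without wild-type array 5-1 (adjusted p = 0.0559), and its adjusted p ranged from 0.000118 to 0.477 over its alternatives. Of the aquaporin genes, 7 were tested. Aqp1 of the proximal tubule fell 1.64-fold, Aqp2 rose, Aqp3 did not pass (log2 change 0.25, adjusted p = 0.129), and the list as a whole did not pass (camera adjusted p = 0.131), except with the deposited scaling (adjusted p = 0.0287) and with fry (adjusted p = 2.1e-06), over a range up to 0.396. The list had 1 member higher and 2 lower, Aqp11 included, also adjusted over the list alone. Since it holds the deleted gene itself, with a log2 change of -4.92, a fall of the list in any fit is partly built in.

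Genes of cystic kidney disease and the cilium, which bear on the known renal cysts of Aqp11-deficient mice, did not pass as a list. Of 25 tested members 1 rose and 1 fell, with a median log2 change of -0.05 (camera adjusted p = 0.282), and adjusted over the list alone only 1 fell. Pkd1 had a log2 signal of 7.13 ± 0.11 (SD, n = 7) in wild type and 7.12 ± 0.16 (SD, n = 9) in knockout, a log2 change of -0.01 (adjusted p = 0.955). Pkhd1 went from 10.10 ± 0.18 to 9.87 ± 0.18, a log2 change of -0.23 that did not pass (adjusted p = 0.0671). This call depended on the arrays and the fit: Pkhd1 passed as lower in males alone (adjusted p = 0.0279), with array weights (adjusted p = 0.041), and without wild-type array 2-1 (0.0465) or 5-1 (0.0197) or knockout array 3-2 (0.0368) or 3-3 (0.0394). It also passed with the first sample number as a block (adjusted p = 0.00235) and with sex added to that block (0.00358), though the labels do not say that this number marks a litter. Over all its alternatives its adjusted p ranged from 0.00235 to 0.9995, the last with the deposited scaling. Sec63 rose 1.21-fold and Glis2 fell 1.21-fold, while Bbs2 (log2 change -0.31, adjusted p = 0.0692) did not pass. Pkd2 was not analysed here.

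Proliferation and cell death genes did not pass as groups. Among 35 cell cycle genes only Ccnd1 passed, 1.29-fold lower, while the list median was 0.13 (camera adjusted p = 0.127) and none passed adjusted over the list alone. Cdc6 (0.48), Ccne1 (0.34) and Plk1 (0.27) had positive log2 changes that did not pass. Without knockout array 1-2, the cell cycle list had a median of 0.22 and passed with a camera adjusted p of 8.84e-05. It also passed with array weights, in males alone and on the dimmer arrays alone, with a range up to 0.759 over its alternatives. Among 29 apoptosis genes 4 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.282), and the list passed only with fry (adjusted p = 0.0011, range up to 0.464). The rises were those of Casp12 (2-fold), which encodes a caspase of the endoplasmic reticulum, Birc3 (1.76-fold), Casp4 (1.87-fold) and Tnfrsf1a (1.32-fold). Oxidative stress and NRF2 genes rose for 6 and fell for 11 of 33 members, 7 and 13 adjusted over the list alone (camera adjusted p = 0.102). This list passed as lower in 5 of its 37 alternatives, with a range from 0.036 to 0.434, among them males alone and the fit without knockout array 1-2 (adjusted p = 0.0499). Gsta2 (1.42-fold), Gsta3 (1.64-fold) and Gpx3 (1.37-fold) fell and Gstp1 (1.21-fold) rose.

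Several other lists held changed genes without passing as a whole. Podocyte genes rose for 1 and fell for 5 of 18 members, 2 and 6 adjusted over the list alone (camera adjusted p = 0.0823), with lower Clic5 (1.37-fold), Nphs1 (1.44-fold), Ptpro (1.3-fold) and Plce1 (1.24-fold). Without wild-type array 1-1 this list passed (adjusted p = 0.0153), as it did in females alone, on the dimmer arrays alone and with fry, with a range up to 0.377 over its alternatives. Nephrogenic progenitor genes rose for 1 (Wnt4, 1.28-fold) and fell for 3 (Itga8, Wnt11 and Jag1, 1.24-fold to 1.3-fold) of 17 members, with the same counts adjusted over the list alone (camera adjusted p = 0.319), and passed only with fry (adjusted p = 0.0486, range up to 0.542). Vitamin D and calcium genes rose for 1 and fell for 4 of 17, 1 and 5 adjusted over the list alone, and lay just above the threshold (camera adjusted p = 0.0503). It passed as lower in 23 of its 37 alternatives, with a range from 0.00275 to 0.294. Among these were median centring (adjusted p = 0.0351), sex as a term (0.0484) and the brightness groups as a block (0.0302). The first sample number as a block (0.0477), also with sex added (0.0484), was another. So was leaving out wild-type array 1-1, 2-1 or 2-2 or knockout array 1-2, 3-4, 4-3, 4-4 or 5-2 (0.0255 to 0.0486). Slc34a1 (1.56-fold), Kl, Slc34a3 and Pth1r (1.34-fold) were the members that fell. Lysosomal genes rose for 7 and fell for 8 of 32, 8 and 10 adjusted over the list alone (camera adjusted p = 0.378), with higher Ctsc (2.24-fold), Ctsd (1.28-fold) and Ctsb (1.19-fold) and lower Ctsl (1.24-fold).

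Glycolysis and hypoxia genes rose for 3 and fell for 5 of 24 members, 3 and 6 adjusted over the list alone (camera adjusted p = 0.282). The hexokinase gene Hk2 rose 3.2-fold and Pfkp 1.28-fold, while Bnip3 fell 1.39-fold and Egln3 1.44-fold. Cholesterol synthesis genes rose for 1 and fell for 2 of 20, also adjusted over the list alone (camera adjusted p = 0.606), and passed only in males alone (adjusted p = 0.026, range up to 0.995). Fdps rose 1.47-fold, Stard4 and Ebp each fell 1.27-fold, and Idi1 did not pass (log2 change 0.25). Markers of neighbouring tissues were tested as well. Of 6 fat tissue genes only Gpd1 passed, 1.42-fold lower and also adjusted over the list alone, and camera's direction was down (adjusted p = 0.938) although the median and the mean were both 0.14. The fat tissue median rested on single arrays, from -0.07 without wild-type array 4-1 to 0.38 without wild-type array 1-1. The other leading members, Fabp4 (0.07), Pparg (0.22) and Cidea (0.64), did not pass. Of 9 blood genes 3 rose, S100a8 (2.44-fold), S100a9 (1.69-fold) and Hbb-b2 (1.55-fold), and Slc4a1 fell (3 and 2 adjusted over the list alone). The camera test of the blood list was down (adjusted p = 0.945), like its median of -0.03, while its mean was 0.15. Of 3 adrenal genes Mc2r rose 1.64-fold, also adjusted over the list alone, and Star (-0.52) and Pnmt (0.21) did not pass.

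Sex was compared to check the labels and to ask whether the knockout effect differs between males and females. With genotype in the model, 6 genes differed between the sexes. The Y-linked genes Eif2s3y, Kdm5d and Uty had higher signals in every male than in any female, by 6.17, 4.62 and 3.70 on the log2 scale, and Xist lay between 11.3 and 11.8 in females and between 2.78 and 4.70 in males. Eif2s3x (-0.57) and Kdm6a (-0.72), 2 X-linked genes, were lower in males (limma adjusted p = 8.66e-07 and 0.00589). Ddx3y was not analysed here. No gene passed the test of a genotype by sex interaction in limma, where the smallest adjusted p was 0.455 and 1354 genes had an unadjusted p under 0.05. Fitted apart, males gave 1417 changed genes and females 681, and the log2 changes of the sexes correlated with r = 0.609 across genes, which are not independent replicates.

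Genes close to Aqp11 along its chromosome were compared with all others, because the mutant mice were first made in another strain and then crossed to C57BL/6, so that alleles of the first strain can remain around the gene. Of the 100 tested genes nearest to Aqp11, 50 on each side, 36 (36%) were changed, against 17.6% of the other genes tested (odds ratio 2.64, 95% interval 1.70 to 4.04, Fisher's exact p = 1.54e-05, two-sided). With 100 genes on each side, which include those nearest 100, 54 of 200 (27%) were changed. The odds ratio was then 1.74 (95% interval 1.24 to 2.40, Fisher's exact p = 0.00101, two-sided). With the smallest p among them were Ctsc, a lysosomal protease gene that rose 2.24-fold, the acyltransferase genes Mogat2 (2.26-fold lower) and Dgat2 (1.76-fold lower), Aamdc (1.58-fold lower), Sytl2 (1.57-fold higher), the NADPH oxidase gene Nox4 (1.99-fold lower), the folate receptor gene Folr1 (1.57-fold lower) and Myo7a (1.45-fold lower). Trim34a and Trim12a followed at ranks 56 and 57, just outside these 100 genes.

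**Figure D3:**
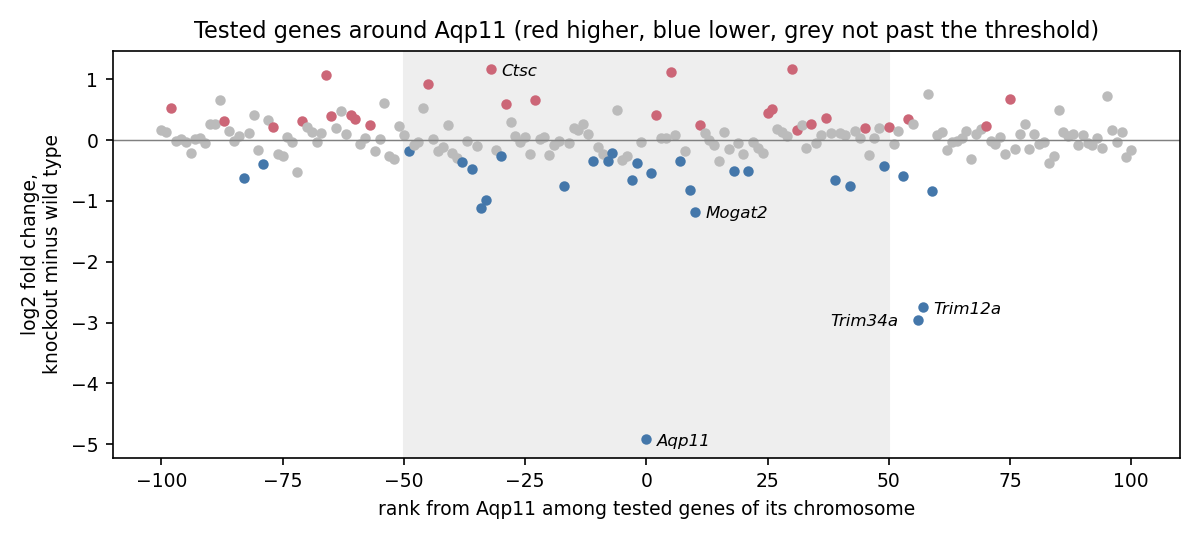
Log2 fold change, knockout minus wild type, of tested genes by their rank from Aqp11 in the gene order of its chromosome, with the 50 genes on each side shaded. Red points rose, blue points fell and grey points did not pass the threshold. Of the 100 shaded neighbours 36 passed, and Trim34a and Trim12a stand out at ranks 56 and 57.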

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

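Among these tests, those of the proximal tubule share, of brightness and the Gapdh ratio for the second component, and of lists with an estimated correlation over other splits were chosen after the result was seen, and the brightness groups and the actin covariate were chosen after seeing the data. Arrays were checked within each genotype for a value far from the rest, over the named genes and the means of the lists. Of 103 groups 12 held such an array, where chance gives about 1 in 20. Each ratio below is the gap to the nearest array over the range of the group. Knockout array 1-2 accounted for 4 of the 12. It was highest for Fgg (ratio 0.522, log2 signal 8.38, others 7.01 to 7.67) and for the mean of the tubular injury list (0.50, 8.95, others 8.45 to 8.70), and lowest for the cell cycle mean (0.691, 7.49, others 8.15 to 8.44) and the cholesterol synthesis mean (0.579, 7.92, others 8.25 to 8.50). Wild-type array 5-1 accounted for another 4. It was lowest for Ankrd1 (0.633, at the floor of 2.78) and the p53 mean (0.607, 7.46, others 7.56 to 7.63), and highest for the endothelial mean (0.81, 9.04, others 8.80 to 8.85) and the glycolysis mean (0.648, 9.50, others 9.14 to 9.26). Knockout array 2-4 was lowest for Ccl2 (0.684, 5.42, others 6.32 to 6.73) and knockout array 2-3 for the proximal tubule mean (0.546, 8.97, others 9.35 to 9.68). Wild-type array 4-1 was lowest for Derl3 (0.574, at the floor of 2.78) and wild-type array 1-1 for the podocyte mean (0.66, 8.84, others 9.01 to 9.10).

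The arrays 1-2 of the knockout and 5-1 of the wild type also mark the ends of the second principal component, at 24.3 and -24.6. The component rose with the trimmed mean signal (Spearman's rho 0.715, permutation p = 0.00256, adjusted p = 0.00384, Pearson's r 0.65, permutation p = 0.00787, adjusted p = 0.0118), also within the brighter (r = 0.623) and the dimmer arrays (r = 0.861), and r was 0.4932 without the 2 arrays farthest from the median signal. It fell with the Gapdh 3' to 5' ratio (rho -0.941 and r -0.925, both with the smallest p that 100000 permutations can give, 1e-05, adjusted p = 3e-05), and r was -0.91 without the 2 farthest arrays. With the actin 3' to 5' ratio it went the opposite way (rho 0.468, permutation p = 0.0688, r 0.591, permutation p = 0.0167, and 0.349 without the 2 farthest). Of these 3 relations, that with the Gapdh ratio was the strongest, also within the brighter (r = -0.904) and the dimmer arrays (r = -0.922). Brightness may account for the component, though its relation was weaker. RNA quality stays open because the control ratios point in different directions. The first sample number (43.6% of the component's variance, permutation p = 0.148) is open too.

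Macrophage genes rose and proximal tubule genes fell in the same kidneys. A lower share of proximal tubule cells as the only change would raise the markers of every other cell type alike. The thick ascending limb and distal tubule list instead fell, with a median of -0.194 (95% bootstrap interval over its genes -0.369 to -0.0887) and 7 of 19 members passing as lower. That interval measures the spread between genes of the list and not between animals. This bears only on such a loss by itself, since more macrophages at the same time could lower that list too. Brightness is not the whole cause, since both lists kept at least 91.6% of their median within each brightness group, and with the actin ratio as a covariate they kept at least 95.1%. More macrophages, a changed state of the tubule cells, a lower share of proximal tubule cells beside these, or several of them, remain as hypotheses. These whole-kidney values do not separate them.

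The knockout effect on 3 lists differed between the sexes by camera's preset correlation. The median log2 difference, male minus female, was 0.347 for collecting duct (adjusted p = 0.00876), 0.183 for extracellular matrix and fibrosis (adjusted p = 0.00233) and 0.31 for cholesterol synthesis (adjusted p = 0.0118). With an estimated correlation none of them passed, the lowest adjusted p being 0.842. No gene passed the interaction test, so all 100 splits of the sex labels within genotype gave at least as many, and the highest other split gave 340. At an unadjusted p under 0.05, 9 of the 100 splits gave at least the 1354 genes of the real labels. For the sex effect itself, 2 of 100 splits, the real one among them, gave at least 6 genes. Xist and Y-linked genes are among these 6, and correct sex labels separate them in advance. The count therefore checks the labels and does not decide on chance. The other split gave 1542 and parted the arrays along the second component (means of -11.0 and 11.0), which points to a structure of the samples other than sex.

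Probe sets that name no gene or several here lie outside the comparisons above. Of 4199 such probe sets tested on their own, 337 changed in the knockout, 156 higher and 181 lower. Their log2 changes included 4.01, above that of every named gene but Havcr1, and -3.52, below that of every named gene but Aqp11, so the ranking of rises and falls covers only probe sets that name 1 gene.

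Other splits of the 16 arrays into groups of 7 and 9 were tested against the real one. Only 1 of 100 splits, the real one, gave as many changed genes (2215, highest other 3) or as many higher (1171, highest other 1). The same held for genes lower (1044, highest other 2) and for genes changed at least 2-fold (280, highest other 0). No other split came near these counts. The genotype effect stays in the residuals of the other splits and can lower their counts, so the size of the gap is not a measure of chance alone. For lists, chance cannot be excluded with the preset correlation, where 18 of 100 splits gave at least 13 lists and the highest other gave 18. With an estimated correlation only 1 split, the real one, gave 9 lists, and the highest other gave 0. In the other splits the genotype effect stays in the residuals and can raise the estimated correlation, so this contrast does not decide on chance.

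Changed genes were more frequent around Aqp11, with 36 of the nearest 100 genes changed and 54 of the nearest 200 (odds ratios 2.64 and 1.74). The excess thus lay mainly within the 50 genes on each side. Only 2 of 427 windows of neighbouring genes along the genome held as many. These windows overlap and may include the region of Aqp11 and Aqp11 itself, so their count is descriptive only. Such an excess is what alleles of the first strain kept around the targeted gene would give. Those alleles may explain part of these changes, apart from the loss of Aqp11. Whether they account for Trim34a and Trim12a, at ranks 56 and 57 and so outside the 50 genes on each side, was not tested. Knockout array 4-3 kept Trim34a within the wild-type range and had the highest Trim12a signal of the knockouts, and why was not tested. A second probe set moved the same way for 53.3% of called neighbours that had one (8 of 15) and for 61.7% of other called genes (Fisher's exact p = 0.595), so whether sequence of the first strain under single probes adds to the excess cannot be told apart from true expression changes with so few neighbours. A regulatory effect of the loss of Aqp11 on these genes was not tested.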

How the results depend on the processing

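The alternatives on brightness, the actin ratio and the second component were added after seeing the data. Aqp11 and the neighbourhood test kept their direction and passed in all alternatives run on them, with odds ratios of 1.74 to 3.05 for the second. The count of changed genes moved from 2215 to 438 (284 higher, 154 lower) with the deposited scaling, and the cause was not tested. Fits on part of the arrays gave fewer, as fewer samples would: 1417 in males (599 lower), 681 in females (362 higher, 319 lower), 1333 on the brighter arrays (653 higher, 680 lower) and 1183 on the dimmer (707 higher, 476 lower). A filter at the 60th percentile, which tests fewer genes, left 149 changed at least 2-fold. Leaving out each array in turn gave 1858 to 2209 changed genes and Aqp11 changes of -5.01 to -4.88. The floor sets the size of that change: -6.53 without one and -3.30 at the 40th percentile, and the mean of its probe sets gave -3.33. The other alternatives kept the counts within 1.5 times. The labels do not say that the first sample number marks a litter, and the data do not settle whether same-numbered arrays pair. Of 13 pairs of a wild-type and a knockout array, 4 had deviations correlated above 0.1 (range -0.14 to 0.32). The median r was 0.0723 for these pairs and -0.0131 for other pairs, and 6 of 16 arrays were closest to their own number. Chance rates for these values were not computed, so the first sample number stays an alternative. With that number as a replicate block 2655 genes changed, 2172 of them shared with the main 2215, and the block ended no call of a count or list. Among the genes named by rank or by name, 887 of 895 comparisons kept their side of the threshold. The other 8 (Pkhd1) gained a call, 2 of them with the block (adjusted p = 0.00235 and 0.00358). Most of these genes were picked for the largest changes of the main fit, so their calls were likely to be kept. Genes named only as members of a list were not part of these comparisons. Among lists 912 of 962 comparisons kept their side, 9 lost a call, 41 gained one, and none turned. Fry called 19 lists. Genes near the floor have only a bound on their fold.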

Other observations

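The lists in this part were written and tested only after the results were seen. Genes induced through ATF4, a factor of the amino acid response, rose for 20 and fell for 2 of 30 tested members, with a median log2 change of 0.40. Among them were the folate cycle genes Aldh1l2 (2.35) and Mthfd2 (1.22), the amino acid transporter genes Slc7a3 (2.06) and Slc7a5 (0.99) and the transfer RNA synthetase genes Gars (0.45) and Aars (0.45). Genes of the IL-6 family and STAT3 rose for 13 and fell for 1 of 19, with a median of 0.57. The oncostatin M receptor gene Osmr (2.21), Socs3 (2.54), Il1rn (2.48) and Stat3 itself (0.92) were among these. Of these 19, 3 belong to a list described above, and the macrophage list rose in the same kidneys (28 of 29, median 1.37). Immediate early genes rose for 17 of 26 and fell for none, with a median of 0.48, as in Fosl1 (2.38), Dusp5 (2.14), Fos (1.25) and Egr1 (1.00). Of these 26, 4 belong to lists described above.

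The hypothesis in each case is that the genes rose together. With members changed at least 2-fold left out, camera with an estimated correlation gave an adjusted p of 0.00845 for the 26 genes left in the ATF4 list (median 0.28), 0.0484 for the 12 in the STAT3 list (median 0.41) and 0.0484 for the 18 immediate early genes (median 0.37). The genes left had also been chosen after their changes were seen, some of them just under 2-fold, so these tests do not decide the hypotheses, which stay open.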
